A study of Mus musculus with 16 samples.

How the data were processed

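Colon RNA of male Il10-/- mice (B6.129P2-Il10tm1Cgn, which lack the anti-inflammatory cytokine interleukin 10) and of male C57BL/6J mice was profiled on 16 Agilent arrays with 2 channels. Per the labels, the mice were given intestinal bacteria by mouth, ate 1 of 4 diets for 6 weeks and were sampled after 77 days of age. Each array received an equimolar pool of colon RNA from 2 to 3 mice in the Cy3 channel and a common reference RNA in the Cy5 channel. The reference was a mix of RNA from gut, kidney and liver of Swiss mice and from fetuses. The 2 genotypes and 4 diets make 8 groups, with 2 pools and so 2 arrays in each. The labels do not say that the pools of a group hold different mice, so p-values measure only the spread between these arrays, part of which may be technical. No dye swap is named in the labels. A dye effect on a probe is then the same on every array and drops out of differences between groups.

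The deposited values are log2 ratios per feature, already processed by the authors. The submitters' processing notes name limma with no version and no role, and the normalization, the background correction and the rule behind missing values are not given in the sources used here. Base 2 is the convention of limma and was not stated, so the log2 scale itself is an assumption. The direction of the ratio was also not stated. It was settled as sample over reference from genes of the reference tissues, whose median lay below 0 on 16 of 16 arrays, between -3.525 and -2.001. The kidney gene Umod averaged -2.83 ± 0.25 (SD, n = 16) and the liver gene Ttr -3.51 ± 0.24. A second list, of colon epithelium genes, was uninformative, because its median lay below 0 on 9 of 16 arrays. The deposited table held 44290 features, of which 41883 had a value on at least 1 array and 31407 on all 16. Array medians lay between -0.019 and -0.001, and 37005 to 40827 features had a value on an array. No brightness was among the values used here, so spots near background and saturated spots could not be told from others, and the number of arrays limits the precision.

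On each array 326 to 985 features shared exactly 1 value, while the next most shared value occurred 3 or 4 times. The features at that value included the mucin gene Muc2 and the carbonic anhydrase gene Car1 on 16 of 16 arrays. Such a value is written "tied" here. It was kept in the fit and in the list tests like any other value, and set to missing only in an alternative chosen after the data were seen. A tied value may not measure its own gene, so several calls that rest on tied values are named as such. The counts of called list members also hold tied genes that are not named there. Among these are Igtp (tied on 6 of 16 arrays), Acadvl (4) and every probe of Acaa2 (2 to 9). No pair of the 120 pairs of arrays held identical values.

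Gene names came from the platform annotation, in which 32042 features had 1 symbol and 47 had several, and 31906 of the former were matched by gene ID to a table of current mouse gene symbols, which changed 0 symbols. No gene was named from a feature with several symbols. Features with a value in every group (37252) were kept, and the features of a symbol were averaged, which gave 25892 genes and unnamed features: 17995 named genes, 7506 of them with more than 1 probe, and 7897 unnamed features. Another 4631 features with some value were not tested. Feature numbers do not tell repeated spots of a probe from different probes, so all features of a symbol had equal weight. Some genes chosen in advance, Reg3b among them, are not reported.

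Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit with 8 group means over all 16 arrays, contrasts.fit and eBayes). The fit had 8 residual degrees of freedom and a prior of 4.07. P-values were adjusted by Benjamini-Hochberg over the 25892 tests of each contrast, and an adjusted p under 0.05 is called. Differences are given with the standard error (SE) of the fit, and levels as mean ± SD over arrays. The contrasts were genotype averaged over diets and on each diet, EPA against OA, AA against OA, EPA against AA and OA against CO (in each genotype and averaged), any diet difference in each genotype, the interaction, and the difference of the EPA and AA effects between genotypes. Tables were prepared in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

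The groups, the tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The 39 lists of pathway genes and cell type markers were tested with limma's camera at a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over 507 tests (39 lists in 13 comparisons). camera asks whether a list moved relative to all other genes. It was set beside camera with a correlation estimated per list and beside fry, which asks whether a list's genes moved one way on balance. Lists of sex-linked genes, of reference tissues, of colon epithelium and of genes flanking Il10 served as checks. Named genes were the 10 largest positive and the 10 largest negative called differences between genotypes with the same sign on all 4 diets, up to 5 called genes per direction for each diet contrast or, where none was called, the 3 smallest p-values in Il10-/- mice as values only, the 5 smallest p-values of the interaction, up to 4 genes per list with the smallest p, and 27 genes fixed by name that were tested. Clone-type symbols were passed over.

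The test was first run on simulated data with 200 changed genes among 25892. For genotype averaged over diets, it recovered 86.6% of genes changed by 0.5 on the log2 scale and 98.5% of those changed by 1. For EPA against OA in Il10-/- mice, with 2 arrays against 2, the shares were 29.9% and 86.6%. The alternatives were each array's median set to 0, quantile normalization between arrays, features with a value on all arrays, features tested singly, array weights, the pool number as a replicate block, a fit of only the groups compared, and leaving out each array in turn. A further alternative concerns the array titled Il10-/- OA Pool 1, whose source name reads EPA. It was counted as OA, after its title, and as EPA in the alternative. The numbers of the pools were not in the model.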

Results

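Il10-/- mice lack interleukin 10, which restrains immune responses to gut bacteria, and here their colon RNA was compared with that of C57BL/6J mice on 4 diets: CO (AIN-76A, the control diet), OA (oleic acid, the control fatty acid), EPA (eicosapentaenoic acid, an n-3 fatty acid) and AA (arachidonic acid, an n-6 fatty acid). Differences are on the log2 scale with the SE of the fit, and levels are log2 ratios to the reference RNA as mean ± SD.

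Neutrophil and interferon genes were far higher in the Il10-/- colon. S100a9, which encodes a calcium-binding protein of neutrophils, was at 2.28 ± 0.74 in Il10-/- mice and -1.72 ± 0.61 in C57BL/6J mice (n = 8 arrays each), a difference of 4.00 ± 0.21 (adjusted p = 2.49e-07). Its partner S100a8 rose by 2.73 ± 0.15 and the cytokine Il1b by 2.65 ± 0.17. Ubd, a ubiquitin-like gene induced by interferon gamma, rose from -1.94 ± 0.19 to 1.13 ± 0.32 (difference 3.07 ± 0.12), and Ido1, whose enzyme breaks down tryptophan, rose by 2.79 ± 0.14. H2-DMb1, needed to load peptides onto MHC class II, rose by 2.48 ± 0.08 (adjusted p = 3.54e-08), and the T cell attractants Cxcl9 and Cxcl10 by 2.47 ± 0.14 and 2.43 ± 0.17. The interferon-induced GTPase genes Gbp4 and Iigp1 rose by 2.32 ± 0.15 and 3.02 ± 0.13, with Iigp1 at the tied value on 4 Il10-/- arrays. Averaged over diets, 4470 of 25892 genes differed by genotype (2367 higher and 2103 lower in Il10-/- mice), 246 of them by more than 1.

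Il10 itself gave a higher signal in the mutant, 0.58 ± 0.13 against -0.17 ± 0.08 (n = 8 arrays each), a difference of 0.75 ± 0.05 (adjusted p = 2.11e-06). Where the probe lies relative to the targeted part of the gene was not known, so this signal does not measure intact Il10 transcript. Among inflammatory genes chosen in advance, Tnf rose by 1.51 ± 0.07, Ifng by 1.28 ± 0.08, the nitric oxide synthase Nos2 by 0.96 ± 0.11, the iron-binding Lcn2 by 1.30 ± 0.13 and Il6 by 0.32 ± 0.08. Saa3, an acute phase gene, rose by 0.51 ± 0.15 (adjusted p = 0.0337), a call that ended with array weights (adjusted p = 0.0713), with Il10-/- OA replicate 1 counted as EPA (0.0545) and without 8 of the single arrays in turn (0.0528 to 0.0846). The antimicrobial gene Reg3g was at the tied value on 8 Il10-/- arrays and 5 C57BL/6J arrays, which leaves its difference unmeasured.

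The list of interferon gamma response genes rose as a whole, from -1.04 ± 0.13 to 0.79 ± 0.23 (list mean over 8 arrays each). All 21 of its genes were called higher, 21 also adjusted over the list alone, with a median difference of 1.88 (camera adjusted p = 1.96e-33; adjusted p = 0.0976 with an estimated correlation). MHC class II genes had 8 of 12 called (8 adjusted over the list alone), among them H2-Aa at 1.93, and a median of 1.07 (adjusted p = 4.36e-09, 0.108 with an estimated correlation). MHC class I genes had 7 of 16 called (9 over the list alone), led by the immunoproteasome genes Psmb8 and Psmb9 at 1.80 and 1.76 and the peptide transporter Tap1 at 1.72 (adjusted p = 5.04e-05, 0.211 estimated). The count is not a share of measured genes, because H2-D1, H2-Q5, H2-Q7, H2-T23 and Psmb10 sat at the tied value on all 8 Il10-/- arrays. Type I interferon genes were mixed, with 7 higher and 2 lower of 21 (8 and 2 over the list alone), a median of 0.14 and Zbp1 at 2.14 (adjusted p = 0.00223, 0.504 estimated).

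Markers of immune cells rose with them. Macrophage and monocyte markers had 13 of 16 called higher and 1 lower (14 and 1 adjusted over the list alone), with a median of 0.66. Examples were Aif1 at 1.28 ± 0.08, the Fc receptor Fcgr1 at 0.99 ± 0.06 and C1qc at 0.77 ± 0.05. Chemokines (14 of 22 called higher, median 0.57, Ccl2 at 1.27) and complement genes (10 of 16, median 0.55, C4b at 1.07 and C1ra at 1.38) rose as well, with 16 and 11 higher over the list alone. These 3 lists were the ones whose rise also passed with an estimated correlation (adjusted p = 0.0458, 0.0369 and 0.0458), after 5.53e-15, 8.54e-12 and 6.36e-10 at the preset. Neutrophil markers had 9 of 13 called (11 over the list alone, median 0.46, Ltf at 0.87 ± 0.06; adjusted p = 5.13e-10, 0.0858 estimated). Cytotoxic cell genes had 7 of 11 called (7 over the list alone, median 0.28, Gzma at 1.78 ± 0.10, Gzmb at 0.94 ± 0.08; adjusted p = 9.97e-07, 0.081 estimated). T cell markers had 8 of 14 called (9 over the list alone, Il2rb at 0.72; adjusted p = 4.3e-05, 0.081 estimated), and plasma cell markers 8 of 11 (8 over the list alone, Pou2af1 at 0.79 and Ighm at 0.61; adjusted p = 3.12e-06, 0.139 estimated). B cell markers had 3 of 12 called (4 over the list alone, Cd79b at 0.89; adjusted p = 0.00386, 0.231 estimated). Mast cell markers did not pass as a list (camera adjusted p = 0.0599), with Mcpt1 at -0.82 and Hdc at 0.67, nor did eosinophil markers (adjusted p = 0.65).

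Epithelial defence, repair and division genes were also higher. Acute phase and antimicrobial genes had 13 of 25 called higher (15 adjusted over the list alone, median 0.29, adjusted p = 9.97e-07, 0.0983 estimated), among them the protease inhibitor Slpi at 1.99, the oxidase partner Duoxa2 at 1.51 and the phospholipase Pla2g2a at 1.25. Inflammatory cytokines had 10 of 21 called higher (10 higher and 1 lower over the list alone, median 0.20, adjusted p = 4.11e-05, 0.0991 estimated). Matrix remodelling genes had 8 higher and 1 lower of 20 (9 and 3 over the list alone, adjusted p = 0.00491, 0.395 estimated), with the metalloproteinases Mmp3, Mmp10 and Mmp13 at 1.96 ± 0.12, 1.67 ± 0.18 and 1.35. Cell proliferation genes had 12 of 23 called higher (17 over the list alone, median 0.29, Aurka at 0.57; adjusted p = 1.43e-07, 0.461 estimated). Endoplasmic reticulum stress genes had 9 of 23 (13 over the list alone, adjusted p = 0.00237, 0.25 estimated), with Manf, tied on 3 arrays, at 0.55. Cholesterol synthesis genes had 3 of 20 (6 over the list alone, Fdps at 0.40, adjusted p = 0.00368, 0.564 estimated).

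Genes for handling drugs, toxins and fatty acids were lower in the Il10-/- colon. Ces1g, a carboxylesterase, averaged -0.65 ± 0.85 in Il10-/- mice and 1.76 ± 0.24 in C57BL/6J mice (n = 8 arrays each), so it fell by 2.41 ± 0.20 (adjusted p = 5.12e-06). The deacetylase Aadac fell by 2.46 ± 0.17, the cytochromes P450 Cyp4b1 and Cyp2c29 by 2.32 ± 0.30 and 2.03 ± 0.20, the peroxisomal oxidase Hao2 by 2.27 ± 0.14 and the sulfotransferase Sult1c2 by 1.97 ± 0.12. Cubn, S100g, St3gal5 and Ces1d completed the 10 largest decreases, at -2.07 ± 0.37, -1.96 ± 0.39, -1.85 ± 0.20 and -1.83 ± 0.17. Xenobiotic metabolism genes had 27 of 47 called lower (32 adjusted over the list alone), with a median of -0.41 and Ugt2b5, a glucuronidating enzyme, at -1.05 ± 0.06 (adjusted p = 3.49e-15, 0.0937 estimated). The list of fatty acid oxidation genes and targets of the fatty acid receptor PPAR alpha had 29 lower and 1 higher of 38 (31 and 1 over the list alone), with a median of -0.45 (adjusted p = 3.49e-15, 0.144 estimated). The receptor gene Ppara fell by 1.15 ± 0.08, Pdk4, whose kinase spares glucose in favour of fat, by 1.66 ± 0.11, Hadh by 0.67 ± 0.06 and Cpt1a by 0.43 ± 0.09. Pparg fell by 0.26 ± 0.06. Angptl4 fell by 0.74 ± 0.21 (adjusted p = 0.0303), a call that ended with quantile normalization (adjusted p = 0.0581) and without several single arrays (0.0555 to 0.0712). Cyp4a10 fell by 0.15 ± 0.05 (adjusted p = 0.0468), a call that ended in many alternatives (adjusted p up to 0.327, with quantile normalization). Tested singly, its probes disagreed, at -0.47 (adjusted p = 0.0102), 0.04 (0.764) and -0.03 (0.835).

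Fat and muscle genes were lower too. Adipocyte markers, genes of fat cells, had 11 of 13 called lower (12 adjusted over the list alone) with a median of -0.82 (adjusted p = 1.04e-07, 0.393 estimated). Adipoq fell by 1.47 ± 0.24 and Lpl by 1.39 ± 0.19, while Scd1, a desaturase also abundant in fat, fell by 1.11 ± 0.31 (adjusted p = 0.0246), a call that ended without several single arrays (adjusted p = 0.0545 to 0.061). The list mean was -0.20 ± 0.19 in Il10-/- mice and 0.65 ± 0.50 in C57BL/6J mice, and Thrsp, a lipogenic gene of fat tissue, moved with it at -1.53. Smooth muscle markers had 9 of 16 called lower (10 over the list alone, median -0.29, Lmod1 at -0.62; adjusted p = 4.06e-06, 0.132 estimated). Fatty acid synthesis genes had 11 lower and 2 higher of 28 (12 and 2 over the list alone, Acsl3 at -1.26 ± 0.08; adjusted p = 0.01, 0.54 estimated). Of the desaturases, Fads2 rose by 0.25 ± 0.06 and Fads1 did not differ detectably (0.01 ± 0.11, adjusted p = 0.962).

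Several lists fell by less. Colonocyte genes had 8 lower and 2 higher of 28 (9 and 2 adjusted over the list alone; adjusted p = 0.00481, 0.294 estimated), with the carbonic anhydrase Car2 at -1.33, the drug pump Abcb1a at -1.42 and the chloride exchanger Slc26a3 at -0.65 ± 0.14. Its probes ranged from -1.03 to -0.14. Enteroendocrine genes had 6 of 20 lower (6 over the list alone, Chga at -0.78 and Cpe at -1.01; adjusted p = 0.00128, 0.465 estimated). Endothelial markers had 6 lower and 2 higher of 17 (9 and 2 over the list alone, Emcn at -0.65, Icam1 at 0.98; adjusted p = 0.0428, 0.569 estimated). Pancreatic enzyme genes had 2 of 16 lower (2 over the list alone, Clps at -1.08 ± 0.21; adjusted p = 0.0276, 0.494 estimated) and mitochondrial respiration genes 1 of 26 (1 over the list alone, median -0.10, Ppargc1a at -0.35; adjusted p = 0.0276, 0.574 estimated). Probes tied on all 16 arrays, such as that of Muc2 and 1 of Cs, themselves read -0.12 in this comparison. The respiration median is no larger than that, so a fall of this list is not separated from a shift of the tied value. The check list of colon epithelium genes lay lower as well (1 higher and 6 lower of 23 genes, camera adjusted p = 2.56e-05, as a single list), with 6 to 8 of its genes tied on each array. Those of sex-linked genes (median 0.08, adjusted p = 0.274) and reference tissues (median -0.14, adjusted p = 0.112) did not differ detectably.

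Genes that make and clear eicosanoids, the signalling lipids derived from AA and EPA, went both ways. The phospholipase Pla2g5 rose by 2.26 ± 0.12, Ptgs2, which makes prostaglandin precursors, by 0.37 ± 0.07, Alox5ap by 0.56 and the thromboxane synthase Tbxas1 by 0.31. Alox5 fell by 0.17 ± 0.04 and the prostaglandin-clearing Hpgd by 0.67 ± 0.14, and Alox15 did not pass (0.12 ± 0.06, adjusted p = 0.209). The list had 7 higher and 10 lower of 37 and did not move as a whole (median -0.01, mean 0.05, adjusted p = 0.716). Junction genes also went both ways, with 4 higher and 4 lower of 22 (adjusted p = 0.474), Cldn8 at -1.58 ± 0.13 and Cldn12 at 0.53. No shift of the whole list was found for oxidative stress defence (adjusted p = 0.216, Gclc at -0.78), crypt base (0.349, Nkd1 at -0.65), neurons and glia (0.0599, S100b at -0.45), collagen and stroma (0.933, Thy1 at 0.44), circadian clock (0.978, Nfil3 at 0.81) or immediate early genes (0.555, Egr2 at 0.48). Goblet cell genes did not move either (adjusted p = 0.699), but Muc2 and several others sat at the tied value, as did the colonocyte gene Car1. The water channel Aqp8, tied on 1 Il10-/- and 6 C57BL/6J arrays, did not pass (-0.46 ± 0.27, adjusted p = 0.286). In all, camera called 28 of 39 lists by genotype, 18 higher and 10 lower, fry 23, and camera with an estimated correlation 3.

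**Figure D1:**
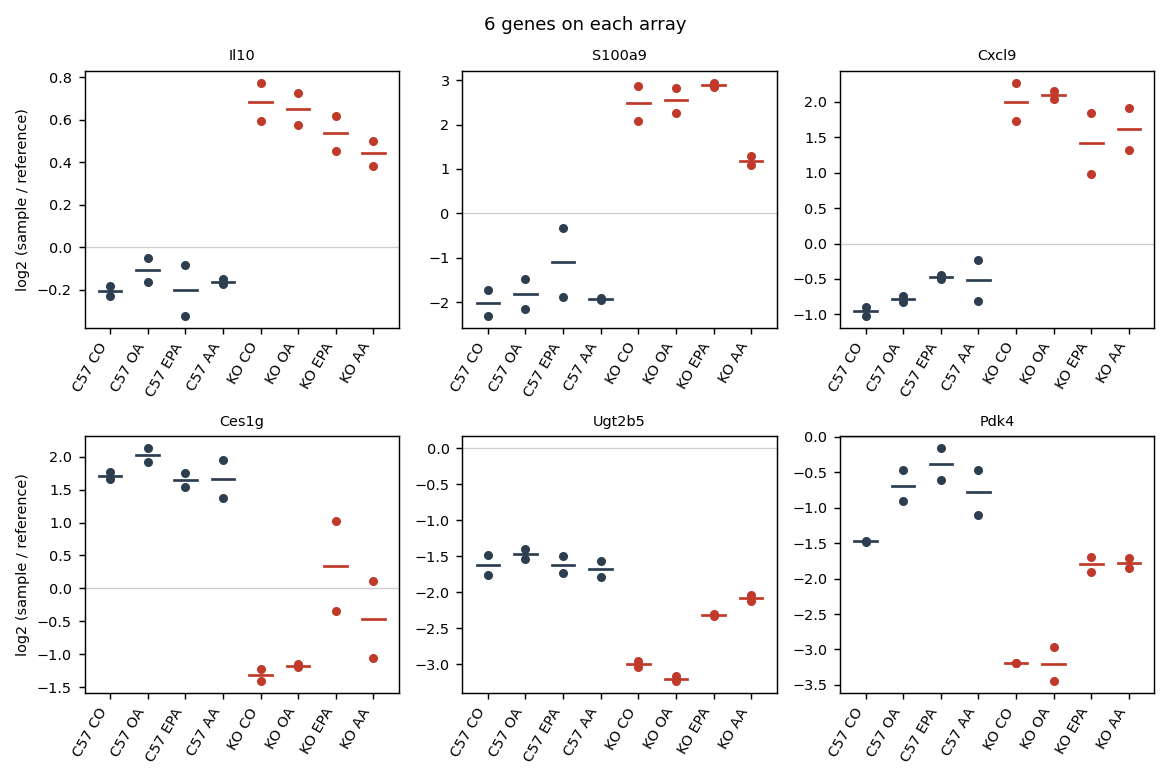
Log2 ratio to the reference RNA (vertical axis) of 6 genes in the 8 groups of genotype and diet (horizontal axis), with points for the 2 arrays per group and bars for group means; KO is Il10-/- and C57 is C57BL/6J. S100a9 averaged 2.28 in Il10-/- and -1.72 in C57BL/6J arrays, and Ugt2b5 was at -3.20 on OA and -2.08 on AA in Il10-/- mice.

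Genotype differences appeared on every diet, in unequal numbers. On CO 2220 genes were called (1318 higher, 902 lower), on OA 1309 (757 and 552), on EPA 421 (309 and 112) and on AA 341 (232 and 109), while 6134, 4042, 3101 and 2847 passed an unadjusted p under 0.05. If no gene differed, 1295 of the 25892 tests would pass that threshold by chance, in these and in all later contrasts. Ptgs2 differed by 0.92 on CO (adjusted p = 0.00156) but not detectably on OA (0.36, adjusted p = 0.197), EPA (0.26, 0.503) or AA (-0.04, 0.948). The interaction of genotype and diet was called for 0 genes, so these values do not show that the Ptgs2 difference depends on diet. Between diets 0 genes were called in opposite directions, and 168 were called higher and 30 lower on all 4. CO and OA shared 561 genes called higher, where independence would give 38.5, and EPA and AA shared 174 (2.8). Across genes, which are not independent replicates, the differences on pairs of diets correlated between 0.50 and 0.75. The counts depended on single arrays, since each group has 2. The CO count was 4025 without C57BL/6J CO replicate 1, 1052 without Il10-/- CO replicate 1 and 764 without Il10-/- CO replicate 2. The OA count was 675 and 621 without C57BL/6J OA replicate 1 and 2, and 665 and 615 without those of Il10-/- mice. For EPA the same 4 values were 160, 264, 248 and 160, and for AA 95, 179, 52 and 150. The order of the diets turned in several settings. CO fell below OA and AA with array weights (CO 630, OA 2834, AA 654) and with only the groups compared (175, 2283 and 197). EPA fell below AA in those settings (333 and 97) and with quantile normalization (404 against 466). OA fell below EPA when Il10-/- OA replicate 1 was counted as EPA (670 and 764).

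In Il10-/- mice the EPA diet went with higher levels of detoxification, fatty acid oxidation and hormone cell genes than the OA diet. Ugt2b5 was at -2.32 ± 0.02 on EPA and -3.20 ± 0.06 on OA (n = 2 arrays each), Pdk4 at -1.80 ± 0.15 and -3.20 ± 0.35, and the sodium exchanger Slc9a3 at 0.42 and -0.63. At an unadjusted p under 0.05 there were 1106 genes, below the 1295 expected by chance. limma called 0 single genes (smallest adjusted p = 0.182, for Ugt2b5), so the levels above are given as values only. The count was 1 without Il10-/- OA replicate 2 and 5 without C57BL/6J CO replicate 2, where Ugt2b5 (adjusted p = 0.0321) and Slc9a3 (0.0461) were called, and 2 with array weights (Ugt2b5 at 0.0211). As a list, xenobiotic metabolism genes rose (41 of 47 above 0, median 0.28, 12 adjusted over the list alone; adjusted p = 3.98e-17, 0.0783 with an estimated correlation), with Aldh1a1, tied on 1 Il10-/- array, at 1.05 ± 0.18 and Sult1a1 at 1.41 ± 0.26. Fatty acid oxidation genes rose (34 of 38 above 0, median 0.22, 3 over the list alone; 8.47e-13, 0.152 estimated). So did enteroendocrine genes (19 of 20, median 0.27, 6 over the list alone, Chgb at 0.87 ± 0.20; 5.38e-11, 0.135 estimated) and colonocyte genes (22 of 28, median 0.22, 3 over the list alone; 6.63e-05, 0.136 estimated). Cholesterol synthesis genes fell (19 of 20 below 0, median -0.22, 2 over the list alone, Fdps at -0.45 ± 0.11; 2.09e-09, 0.206 estimated). Macrophage markers (15 of 16 below 0, median -0.21, 0 over the list alone; 3.32e-05, 0.144 estimated) and interferon gamma genes (18 of 21, median -0.21, 1 over the list alone, Gbp4 at -1.18 ± 0.29; 7.94e-05, 0.506 estimated) fell too. Proliferation genes (21 of 23, median -0.22, 0 over the list alone; 1.08e-06, 0.461 estimated) and complement genes (12 of 16, median -0.18, 0 over the list alone; 0.00079, 0.112 estimated) also fell. camera called 16 lists here, fry 1 and camera with an estimated correlation 0.

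In Il10-/- mice the AA diet went with lower neutrophil and matrix remodelling genes than the OA diet, a contrast that shares its OA arrays with that of EPA and so is not independent of it. Ugt2b5 rose by 1.12 ± 0.12 (adjusted p = 0.0172), from -3.20 ± 0.06 to -2.08 ± 0.06 (n = 2 arrays each), the single gene called (1852 at an unadjusted p under 0.05). The call ended without Il10-/- AA replicate 2 (adjusted p = 0.261), OA replicate 1 (0.506) or OA replicate 2 (0.134), with quantile normalization (0.445), with only the groups compared (0.0634) and with OA replicate 1 counted as EPA (1). The number of genes called was 7 without Il10-/- AA replicate 1, 3 without C57BL/6J CO replicate 2 and 48 with array weights. S100a9 stood at 1.19 ± 0.15 on AA and 2.54 ± 0.41 on OA, Il1b at 1.96 ± 0.17 and 3.31, and Mmp3 at 1.47 and 2.63. Neutrophil markers fell as a list (13 of 13 below 0, median -0.33, 7 adjusted over the list alone, S100a8 at -1.46 ± 0.31; adjusted p = 2.11e-08, 0.108 with an estimated correlation). So did matrix remodelling genes (18 of 20, median -0.29, 8 over the list alone, Mmp13 at -1.16 ± 0.25; 1.99e-07, 0.112 estimated). Macrophage markers (14 of 16 below 0, median -0.24, 5 over the list alone; 1.33e-05, 0.136 estimated) and cytokines (13 of 21, 4 over the list alone, adjusted p 0.00552, 0.236 estimated) fell as well. So did complement (median -0.27, 1 over the list alone; 0.00112, 0.147 estimated) and interferon gamma genes (18 of 21, median -0.21, 0 over the list alone; 0.0037, 0.621 estimated). Xenobiotic metabolism genes rose (41 of 47 above 0, median 0.26, 7 over the list alone; 8.01e-09, 0.136 estimated). Also higher were enteroendocrine genes (17 of 20, median 0.24, 8 over the list alone, Chga at 0.77 ± 0.16; 3.56e-07, 0.206 estimated) and fatty acid oxidation genes (29 of 38, median 0.14, 2 over the list alone, Pdk4 at 1.42 ± 0.22; 5.19e-05, 0.445 estimated). camera called 15 lists, fry 2 and camera with an estimated correlation 0.

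**Figure D2:**
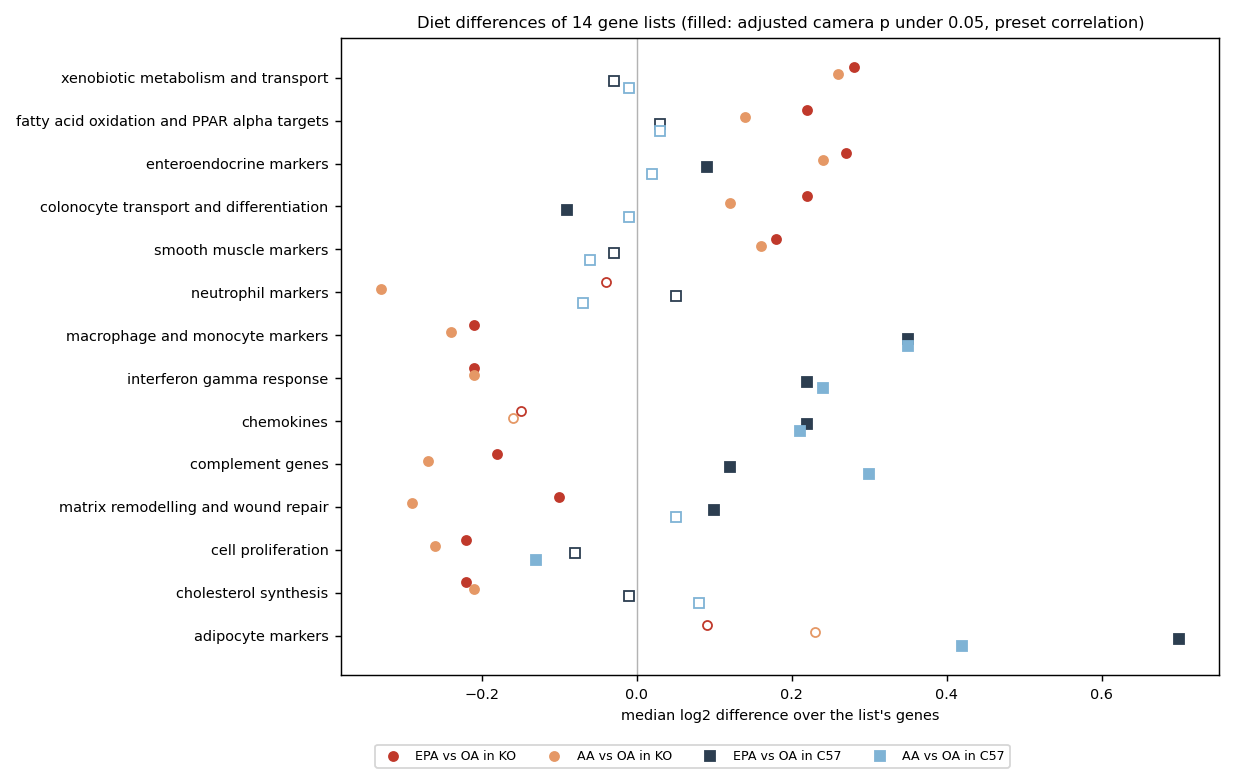
Median log2 difference over the genes of 14 lists (horizontal axis) for EPA against OA and AA against OA, in Il10-/- mice (KO, circles) and C57BL/6J mice (C57, squares), filled where camera's adjusted p at the preset correlation was under 0.05. Macrophage markers lay at -0.21 and -0.24 in Il10-/- mice and at 0.35 on both diets in C57BL/6J mice.

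Set against each other in Il10-/- mice, the EPA and AA diets parted on neutrophil genes. The neutrophil list was higher on EPA (12 of 13 above 0, median 0.30, 5 adjusted over the list alone; adjusted p = 1.45e-08, 0.112 with an estimated correlation), with S100a8 at 1.73 ± 0.31 and the antimicrobial peptide gene Camp at 0.91 ± 0.16. Ptgs2, at 0.70 on EPA and -0.12 on AA, differed by 0.82 ± 0.14 and Il1a by 0.57 ± 0.10. An immunoglobulin kappa variable gene had the smallest p (adjusted p = 0.14), and limma called 0 genes (879 at an unadjusted p under 0.05), or 4 without Il10-/- AA replicate 1 and 1 without AA replicate 2. Cytotoxic cell genes were lower on EPA (10 of 11 below 0, median -0.26, 2 over the list alone, Gzmc at -0.73 ± 0.19; 4.21e-06, 0.0561 estimated). Type I interferon genes (19 of 21 above 0, median 0.15, 0 over the list alone; 6.3e-05, 0.393 estimated) and matrix remodelling genes (17 of 20, median 0.10, 2 over the list alone; 0.000231, 0.236 estimated) were higher. camera called 7 lists and camera with an estimated correlation 0. The 1 list called by fry was that of cytotoxic cell genes (fry adjusted p = 0.0281), while neutrophil markers did not pass it (0.0621).

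Between the OA and CO diets the Il10-/- colon differed little. Macrophage markers were higher on OA (15 of 16 above 0, median 0.25, 3 adjusted over the list alone; adjusted p = 8.47e-15), and this list passed with an estimated correlation (adjusted p = 0.0369). Complement genes were higher too (14 of 16, median 0.20, 2 over the list alone, C1qa at 0.42 ± 0.11; 7.16e-07, 0.0561 estimated). So were plasma cell markers (9 of 11, median 0.24, 2 over the list alone; 1.89e-06, 0.112 estimated). limma called 0 single genes (389 at an unadjusted p under 0.05; 1 without Il10-/- CO replicate 1), and Chil4 at 0.50 ± 0.12 and Tssk3 at 0.46 ± 0.11 had, with C1qa, the smallest p-values (adjusted p = 1 each). camera called 8 lists, 6 higher and 2 lower, and fry 1. The lower lists were pancreatic enzyme genes (15 of 16 below 0, median -0.14, camera adjusted p = 0.000736, 0.25 estimated) and proliferation genes (18 of 23, median -0.09, 0.00648, 0.637 estimated), each with 0 over the list alone.

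**Figure D3:**
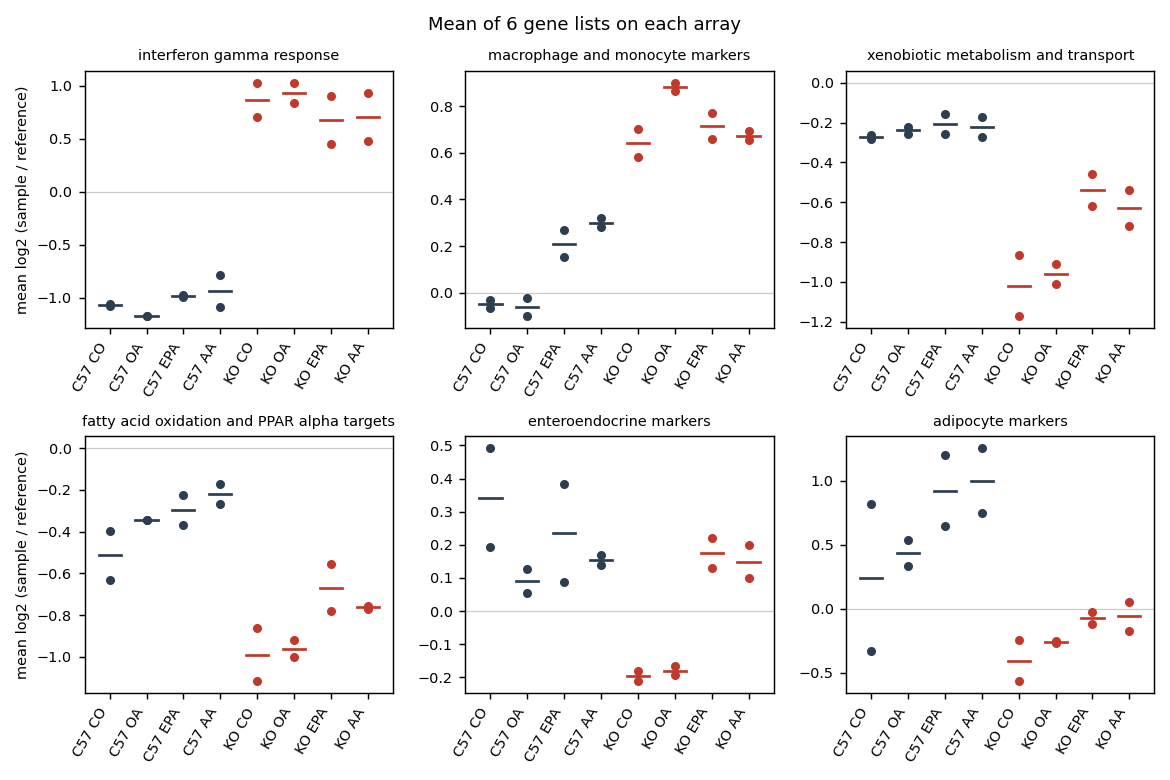
Mean log2 ratio over the genes of 6 lists (vertical axis) in the 8 groups of genotype and diet (horizontal axis), with points for the 2 arrays per group and bars for group means; KO is Il10-/- and C57 is C57BL/6J. Macrophage markers were at 0.88 on OA and 0.67 on AA in Il10-/- mice, and at -0.06 and 0.30 in C57BL/6J mice.

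In C57BL/6J mice macrophage markers were higher on both polyunsaturated diets than on OA, in contrasts that share the OA arrays. The list mean was -0.06 on OA, 0.21 on EPA and 0.30 on AA. On AA 16 of 16 markers lay above 0 (median 0.35, 11 adjusted over the list alone; adjusted p = 3.55e-17, and 0.0369 with an estimated correlation), with the mannose receptor Mrc1 at 0.69 ± 0.15, the scavenger receptor Cd163 at 0.57 ± 0.12 and C1qc at 0.56 ± 0.10. Complement genes rose likewise (14 of 16, median 0.30, 7 over the list alone, C2 at 0.60 ± 0.15; 1.3e-10, and 0.0369 estimated), as did chemokines (20 of 22, median 0.21, 0 over the list alone; 1.66e-06, 0.0587 estimated). On EPA 14 of 16 macrophage markers lay above 0 (median 0.35, 8 over the list alone; 6.88e-09, 0.081 estimated). So did 20 of 22 chemokines (median 0.22, 0 over the list alone; 4.14e-05, 0.0937 estimated) and 13 of 16 complement genes (median 0.12, 4 over the list alone; 0.000105, 0.108 estimated). Adipocyte markers were higher on EPA (median 0.70, Plin1 at 1.08 ± 0.41, 0 over the list alone; 0.00336, 0.574 estimated) and on AA (median 0.42, 0 over the list alone; 0.000165, 0.491 estimated). limma called 0 genes for EPA against OA (1539 at an unadjusted p under 0.05), or 5 without C57BL/6J EPA replicate 2. It called 0 for AA against OA (866), or 2 and 12 without AA replicate 1 and 2, and 0 for EPA against AA (800), or 1 without AA replicate 1. For EPA against AA camera called 4 lists, neurons and glia at 0.05 (adjusted p = 0.00351, 0.255 estimated), type I interferon at 0.07 (0.016, 0.569), endothelial at -0.08 (0.0353, 0.529) and immediate early genes at 0.09 (0.0425, 0.424).

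In C57BL/6J mice 3 genes with measured values were higher on OA than on CO, each at an adjusted p of 0.0279: Ndufs8, of respiratory complex I, by 0.91 ± 0.12, the mitochondrial ribosome gene Mrpl54 by 0.82 ± 0.10 and Mien1 by 0.69 ± 0.09. The partly tied Reg3g made the count 4 (2907 at an unadjusted p under 0.05), and its call ended with tied values set to missing (adjusted p = 0.315). The 4 calls also ended with array weights (adjusted p = 0.395), with the pool number as a block (0.061) and with only the groups compared (0.929). The count was 0 without C57BL/6J CO replicate 2, OA replicate 1 or OA replicate 2, and 2006 without CO replicate 1. The hormone cell gene Chga was at -1.12 ± 0.16 (adjusted p = 0.0831), and enteroendocrine genes fell (17 of 20 below 0, median -0.18, 3 adjusted over the list alone; adjusted p = 0.00024, 0.396 estimated). Cholesterol synthesis genes rose (18 of 20 above 0, median 0.25, 0 over the list alone; 8.45e-06, 0.395 estimated). With 0 genes over the list alone, camera also called proliferation genes (0.14, adjusted p = 0.00256, 0.646 estimated) and fatty acid oxidation genes (0.15, 0.00682, 0.598) higher, and type I interferon genes (-0.14, 0.0354, 0.584) lower. Mitochondrial respiration genes did not move as a whole (3 higher and 8 lower over the list alone, adjusted p = 0.85). Any tied gene reads lower here, because the tied value was 0.103 and 0.615 on the CO arrays and 0.044 and -0.049 on the OA arrays. The check list of colon epithelium genes, partly tied, also had 8 lower over the list alone. How many of the 8 lower respiration genes were tied is not given here. Goblet genes lay lower (median -0.17, 0 over the list alone; 0.00103, 0.168 estimated), with several members at the tied value, which was 0.615 on C57BL/6J CO replicate 2 and between -0.056 and 0.133 on the other arrays. That array also had the fewest tied features, 326 against 592 to 985, and correlated least with the others across features (median r = 0.788, others 0.83 to 0.919). Its adipocyte list mean was 0.82, against -0.33 on the other C57BL/6J CO array.

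The differences of both polyunsaturated diets from OA in macrophage genes were not the same in the genotypes, tested as the difference of the differences (39 lists for each diet, adjusted among themselves). For AA against OA the difference, Il10-/- minus C57BL/6J, had a median of -0.58 for macrophage markers (0 of 16 above 0, 12 adjusted over the list alone; adjusted p = 6.37e-22, 0.00639 with an estimated correlation). It was -0.53 for complement genes (11 over the list alone; 1.76e-12, 0.00639 estimated) and -0.37 for chemokines (0 over the list alone; 1.91e-07, 0.0173 estimated). For EPA against OA it was -0.50 for macrophage markers (9 over the list alone; 1.76e-12, 0.0163 estimated), -0.30 for complement genes (4 over the list alone; 1.6e-07, 0.0163 estimated) and -0.42 for chemokines (0 over the list alone; 9.2e-06, 0.04 estimated). In Il10-/- mice the macrophage list mean was 0.88 on OA and 0.64 on CO, 0.71 on EPA and 0.67 on AA, so the difference rests in part on the OA arrays. Xenobiotic metabolism genes went the other way, at 0.45 for EPA (7 over the list alone; 1.36e-09, 0.057 estimated) and 0.28 for AA (3 over the list alone; 1.36e-09, 0.0532 estimated). limma called 0 single genes in either test (1256 for EPA and 1038 for AA at an unadjusted p under 0.05, or 4 for EPA without C57BL/6J EPA replicate 2 and 2 for AA without Il10-/- AA replicate 1).

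Averaged over genotypes, limma called 0 genes in any of the 4 diet contrasts (1313 at an unadjusted p under 0.05 for EPA against OA, 1714 for AA against OA, 674 for EPA against AA and 1451 for OA against CO). Without C57BL/6J CO replicate 1 the OA against CO count was 835, and no other array left out gave more than 2 in these contrasts. Proliferation genes were lower on EPA (0 of 23 above 0, median -0.14; adjusted p = 5.24e-06) and on AA (0 of 23, median -0.16; 1.04e-07) than on OA, and enteroendocrine genes were higher on EPA (median 0.17; 1.36e-09). Neutrophil markers were higher on EPA than on AA (median 0.14; 4.96e-08), and cholesterol synthesis genes were higher on OA than on CO (median 0.13; 1.61e-05). Of the lists called in the averaged contrasts (9, 12, 11 and 7), 0 passed with an estimated correlation. Any difference among the 4 diets was called for 1 gene in Il10-/- mice, Ugt2b5 (adjusted p = 0.0374; 1255 at an unadjusted p under 0.05), and in C57BL/6J mice for Lyz1 and Reg3g (2098), antimicrobial genes that were tied on 11 and 13 of the 16 arrays. The Il10-/- count was 4 without AA replicate 1, 2 without CO replicate 1, and 0 without CO replicate 2 or any of the EPA and OA arrays. The C57BL/6J count was 873 without CO replicate 1, 6 without AA replicate 1, 12 without AA replicate 2 and 0 without CO replicate 2 or EPA replicate 2. limma called the interaction of genotype and diet for 0 genes (1733 at an unadjusted p under 0.05), or 497 without C57BL/6J CO replicate 1. Chga, Mrpl54, Ugt2b5, Ank3 and Reg3g had its smallest p-values (smallest adjusted p = 0.125).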

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

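The contrast of EPA and AA with CO and OA, the fat tissue test, the test of the doubtful label and the tests on C57BL/6J CO replicate 2 were chosen only after the results were seen.

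Several genes that were low in the Il10-/- colon moved toward C57BL/6J levels on the EPA and AA diets, and fewer genes were called by genotype on those diets (421 and 341) than on OA (1309) and CO (2220), though AA was above CO with array weights (654 and 630) and with only the groups compared (197 and 175). Compared with the CO and OA arrays together, 21 genes were called in Il10-/- mice (2333 at an unadjusted p under 0.05), 20 of them also called by genotype and 19 of those in the opposite direction. Ugt2b5 rose by 0.90 ± 0.08 (adjusted p = 0.00428), Pdk4 by 1.41 ± 0.16, Sult1a1 by 1.53 ± 0.18, Hao2 by 1.36 ± 0.20 and Chga by 0.86 ± 0.12, while the coagulation gene F3 fell by 0.93 ± 0.13. Slc9a3, not called by genotype (0.17, adjusted p = 0.203), rose by 1.00 ± 0.12. Tested with limma as the difference of this contrast between genotypes, 0 genes were called (2200 at an unadjusted p under 0.05, smallest adjusted p = 0.0556). A narrowing of the genotype difference on these diets was thus not established for any single gene. Of the 35 ways to split the 8 Il10-/- arrays into 4 and 4, 1, the real one, gave as many genes (58, highest other 0). That fit had 2 means for the Il10-/- arrays beside the means of the C57BL/6J groups. The 3 splits that keep the pools of each diet together are too few for a share under 0.05. A larger spread between pools on EPA and AA would widen the SE of every diet alike, because the main fit has 1 variance per gene for all groups. The SDs between pools were 0.111, 0.095 and 0.084 on EPA, AA and OA, and 0.135 on CO, which had the most calls. The median genotype difference of the genes called on CO was itself smaller on EPA (0.29) and AA (0.211) than on OA (0.424), by at least 0.13 (EPA minus OA -0.13). These genes were picked on the CO arrays, and both Il10-/- CO arrays correlated best with an OA array, which may favour OA. A wrong label of Il10-/- OA replicate 1, whose source name reads EPA, cannot be told apart for the OA and EPA counts. The AA count compares other arrays, but they share the variance estimate of the fit, and no AA count under the EPA label is given here. On 500 genes picked by 1 EPA array against CO, the doubtful array lay at 0.52 or -0.91 between the other OA array (0) and the other EPA array (1), depending on which EPA array picked. Across genes the array correlated at 0.965 with the other OA array and at 0.949 and 0.94 with the EPA arrays. The other OA array itself correlated at 0.957 with EPA replicate 2, so these values separate the diets little. In the enteroendocrine list the array lay with the other OA array (OA arrays -0.19 and -0.17, EPA arrays 0.13 and 0.22), though that list was chosen for its difference between OA and EPA. Open remain a response to these fatty acids and the order of sampling, which the labels do not give per array.

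Fatty acid oxidation genes were called higher in Il10-/- mice on EPA (median 0.22) and AA (median 0.14) than on OA at the preset correlation, calls lost with an estimated correlation (adjusted p = 0.152 and 0.445). More fat tissue in the samples is a candidate explanation: adipocyte markers averaged -0.07 ± 0.10 on the 4 EPA and AA arrays and -0.33 ± 0.16 on the 4 CO and OA arrays, a difference of 0.27 beside 0.26 for the oxidation list, so both moved in the same direction, as they also did between genotypes. In C57BL/6J mice they moved less alike, with adipocyte means of 0.44 on OA, 0.92 on EPA and 1.00 on AA beside -0.34, -0.30 and -0.22 for the oxidation list, so fat tissue as the whole cause stays open. A general shift toward the C57BL/6J profile cannot be told apart from a separate response of these genes. After the shift common to all genes was removed, the list's median residual exceeded all of the random lists on EPA (0.148, percentile 100) but not on AA (0.025, percentile 83.5), and with a slope corrected for noise the residual was 0.08 (-0.08 to 0.28 over 4 pairings of arrays) on EPA and -0.07 (-0.15 to 0.02) on AA. Activation of the fatty acid receptor PPAR alpha by these diets stays open and was not tested apart from the list itself.

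C57BL/6J CO replicate 2 stood apart: its tied value was 0.615 (other C57BL/6J arrays -0.049 to 0.133), it had 326 tied features (698 to 902), and Muc2 and Car1, at the tied value, read 0.61 (-0.05 to 0.13). The oxidative stress list averaged -0.35 on it (-0.12 to -0.01) and Lcn2 -0.42 (-0.06 to 0.26). It is argued against as the reason that CO has the highest genotype count of the 4 diets, because without it CO had 2759 calls, above OA (1776), EPA (654) and AA (543). With array weights, which gave both C57BL/6J CO arrays 0.32 and the others 0.86 to 1.55, CO (630) fell below OA (2834), as it did with no weights in fits of only the groups compared (175 and 2283), so the order itself depends on the fit. With 2 arrays per group, both arrays of a group get the same weight, so the weights cannot tell which CO array differs. A different brightness setting or dye balance of C57BL/6J CO replicate 2 stays open, since no brightness was used here, and no biological explanation was tested.

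Other arrays lay far from the 7 others of their genotype in single items, by a test that picks about 1 in 20 sets by chance; 17 of 200 sets were picked where chance would give 10. In Il10-/- mice these were, on CO replicate 1, the eosinophil list at -0.23 (others -0.13 to -0.09) and Ubd at 0.38 (1.01 to 1.42); on EPA replicate 1, the eicosanoid list at 0.08 (-0.05 to 0.01) and Cpt1a at 0.46 (-0.20 to 0.04); on EPA replicate 2, the partly tied Iigp1 at 0.66 (-0.22 to 0.06); and on AA replicate 2, Cubn at -3.06 (-4.29 to -3.75). In C57BL/6J mice they were, on EPA replicate 2, the cytokine list at 0.14 (-0.07 to 0.02), S100a9 at -0.34 (-2.31 to -1.49) and Il1b at 1.53 (-0.09 to 0.31). Gbp4 was at -0.52 on AA replicate 2 (-1.01 to -0.81) and Slc26a3 at 0.30 on EPA replicate 1 (0.87 to 1.30).

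The differences of EPA and AA from OA in macrophage, complement and chemokine genes were not the same in the genotypes. Within a genotype most calls were lost with an estimated correlation. In C57BL/6J mice all 3 lists were called higher than on OA at the preset, with estimated values in the order above of 0.081, 0.108 and 0.0937 for EPA and of 0.0369, 0.0369 and 0.0587 for AA. Adipocyte list means rose on the same C57BL/6J arrays, from 0.44 on OA to 0.92 on EPA and 1.00 on AA, and a link between these rises was not tested. In Il10-/- mice macrophage and complement genes were called lower than on OA at the preset (estimated values 0.144 and 0.112 for EPA, 0.136 and 0.147 for AA), and chemokines did not pass (adjusted p = 0.0803 for EPA and 0.0521 for AA). The Il10-/- means on EPA and AA lay near those on CO: 0.71, 0.67 and 0.64 for macrophage markers (OA 0.88), -0.29, -0.33 and -0.31 for complement genes (OA -0.16). With an estimated correlation the adjusted p of the difference was 0.0163, 0.0163 and 0.04 for EPA against OA, and 0.00639, 0.00639 and 0.0173 for AA against OA.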

How the results depend on the processing

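Tests with the tied values set to missing, and those of all comparisons without C57BL/6J CO replicate 2, were chosen only after the data were seen. Averaged over diets the genotype count (4470) stayed within 1.5 times in all settings, from 3586 to 5819 with single arrays left out, and of 174 called values of named genes 0 reversed and 13 lost the call in some setting, while 16 values not called gained one. Array weights gave 630 calls by genotype on CO, 2834 on OA and 654 on AA, and, among diet contrasts, 2 for EPA against OA and 48 for AA against OA in Il10-/- mice, 1 for the AA effect by genotype, 0 for OA against CO in C57BL/6J mice, 14 for any diet in Il10-/- and 1 in C57BL/6J mice, and 1 for the interaction. Fits of only the groups compared gave 175 (CO), 2283 (OA), 97 (EPA) and 197 (AA) by genotype, 1 each for EPA and for AA against OA and 0 for OA against CO in C57BL/6J mice, and 0 for AA against OA and 4 for any diet in Il10-/- mice. With Il10-/- OA replicate 1 counted as EPA the genotype counts were 670 on OA and 764 on EPA, and AA against OA and any diet in Il10-/- mice had 0. Quantile normalization gave 0 for AA against OA and for any diet in Il10-/- mice, 1 for EPA against AA averaged and 2 for the interaction, and lowered the share of higher genes in OA against CO in C57BL/6J mice from 100 to 80%. Medians set to 0 (any diet in Il10-/- mice 0), features tested singly (3 there, 0 for OA against CO in C57BL/6J mice), the replicate block (0 for OA against CO and 6 for any diet in C57BL/6J mice) and tied values set to missing (0 for any diet in C57BL/6J mice) moved the other counts by less than 1.5 times, as did features with a value on all 16 arrays for every count. For all of these, the cause was not tested. The pool numbers were not taken as pairs, a step that needed every correlation of the pool differences between groups to exceed 0.1: 11 of 28 did (-0.35 to 0.38, median 0.06). Pool 1 had more tied features than pool 2 in 8 of 8 groups. Across features, all arrays but Il10-/- AA replicate 2 correlated best with an array of another diet in their genotype. Of these, all but C57BL/6J OA replicate 1, Il10-/- AA replicate 1 and Il10-/- EPA replicate 2 matched an array of the same pool number. Il10-/- CO replicate 1, for example, matched OA replicate 1 (r = 0.959, against 0.941 with its other pool). The pools of a diet thus did not group together, and some technical difference by pool number stays open.

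With single arrays left out, where a lone array is assumed to vary like the other groups, the counts by genotype ran from 764 to 4025 on CO, 615 to 1776 on OA, 160 to 654 on EPA and 52 to 543 on AA, the highest of the last 3 without C57BL/6J CO replicate 2, an array of none of those groups. EPA against OA ran from 0 to 1 averaged, 0 to 5 in Il10-/- and 0 to 5 in C57BL/6J mice, AA against OA from 0 to 1, 0 to 7 and 0 to 12, EPA against AA from 0 to 2, 0 to 4 and 0 to 1, and OA against CO from 0 to 835, 0 to 1 and 0 to 2006. The effects by genotype ran from 0 to 4 for EPA and 0 to 2 for AA, any diet from 0 to 4 in Il10-/- and 0 to 873 in C57BL/6J mice, and the interaction from 0 to 497, the last 2 highest without C57BL/6J CO replicate 1. Of 148 called list tests, 6 were also called with an estimated correlation and 32 by fry, which called 33 tests in all. Of the 148, the call ended for 17 with quantile normalization, 6 with tied values set to missing and 1 with the replicate block, and 15 calls ended over the fits without Il10-/- OA replicate 1 and without C57BL/6J CO replicate 2. The number of arrays limits the precision, and signal over background could not be judged without brightness.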

Other observations

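The tests on the splits of the averaged diet contrasts were chosen only after the results were seen.

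In Il10-/- mice neutrophil genes were lowest on AA, with S100a9 at 1.19 ± 0.15 against 2.48 ± 0.56 on CO, 2.54 ± 0.41 on OA and 2.90 ± 0.07 on EPA (n = 2 arrays each), and the neutrophil list mean at 0.22 against 0.60 to 0.71. Ugt2b5 stood at -2.32 ± 0.02 on EPA and -2.08 ± 0.06 on AA against -3.00 ± 0.06 on CO. In C57BL/6J mice, 5 genes were higher on EPA and AA than on CO and OA together (2007 at an unadjusted p under 0.05): 1 unnamed feature, Lyz1 and Reg3g, partly tied, the Paneth cell defensin Defa22 by 2.35 ± 0.32 and Gpnmb, a gene of lipid-laden macrophages, by 1.62 ± 0.21, all named after their values were seen. Averaged over genotypes Pdk4 alone was called (0.95 ± 0.11, adjusted p = 0.0497).

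Across genes, which are not independent replicates, the EPA minus OA and AA minus CO differences in Il10-/- mice, which share no array, correlated at 0.42, and EPA minus CO with AA minus OA at 0.35. EPA minus AA and OA minus CO correlated at 0.07. The C57BL/6J values were 0.11, 0.34 and -0.25.

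The genotype count was set beside other splits of the arrays within diets: of 100 drawn, 1, the real one, gave as many genes (4470, highest other 2282). A random grouping of these arrays is thus argued against. A split unlike the real one leaves the genotype difference inside its groups, which lowers its count. The pools of a group may share mice, so chance between animals is not excluded. The highest other split kept the real grouping in all but 1 diet on balance, and the 32 splits with no diet on balance like the real one gave 0. For the 4 diet contrasts averaged over genotypes, the 18 possible splits each are too few for a share under 0.05. The real count was 0 in each, and the highest other was 0 for EPA against OA, AA against OA and OA against CO. For EPA against AA it was 33, and 6 of the other splits called any gene. Whether this is chance or a structure of the samples was not tested.

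A segment of chromosome carried along from the strain in which the Il10 mutation was made could place differing genes near Il10. Of the genes around it, 24 were called by genotype (11 higher and 13 lower), 18.6% against 19.7% elsewhere, and 41.7% of 127 other windows had a lower share, with a 95th percentile of 27.8%. An excess of called genes near Il10 was thus not found, while single neighbours such as Rab7b at -1.40 and Mgat5 at -1.32 stay open.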
